A study of Mus musculus with 8 samples.

How the data were processed

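Whole lungs of C57BL mouse embryos at E17.5 were sequenced after the oesophagus, trachea and bronchi had been removed, per the labels' protocols. Total RNA was DNase treated and made into libraries with a TruSeq v2 kit, per the labels' protocols. Groups were taken from the sample labels: control or mutant, female or male, with 2 libraries in each of the 4 groups. The labels say that mutants carried a constitutively active TGF-β receptor 1 in lung epithelium.

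The submitters' processing notes name cutadapt 1.13, Trimmomatic 0.35, STAR 2.5.2b, HTSeq 0.6.1p2 and edgeR 3.16.5, with no role or order. The genome build and the annotation are not given in the sources used here, nor is how strand and shared reads were treated in counting. The authors deposited 1 table of 19150 genes, with raw read counts per library, per the file headers. The same deposited table holds RPKM values per library, gene lengths, and the authors' own comparison of mutant with control as log2 fold change and mean log2 CPM, a likelihood ratio score, a p-value and a false discovery rate, per the file headers. The terms of the authors' model are not given in the sources used here. The lowest gene total in the deposited counts was 28 reads, so genes with fewer reads had been left out before deposit. Dividing the deposited counts by the RPKM values and lengths gave 1 constant library size per library. The tests here used the counts only, and the deposited comparison was used as an alternative.

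Coordinates come from the GENCODE M21 annotation of GRCm38, matched by Ensembl gene ID, and were not used in any test of expression. All deposited counts belonged to genes with an Ensembl ID, some of them unnamed predicted genes. Depth was 17561012 to 20243205 reads in genes per library, and TMM factors ran from 0.975 to 1.02. A gene with few reads, such as Krt17 in controls, is therefore given in reads. The 2 libraries of each group were compared by a chi-square of their counts over genes and by rank correlation before they were used as replicates.

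Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr with a minimum count of 10 (18164 of 19150 genes kept), quasi-likelihood fits and F tests, and Benjamini-Hochberg adjustment at 0.05. The genotype effect and the sex effect over all 8 libraries came from an additive model of sex and genotype. The genotype effect in females and in males, their difference (the interaction) and the sex effect within controls and within mutants came from 4 group means, all 8 libraries sharing 1 estimate of the spread. CPM values were scaled by the TMM-adjusted library size, and log2 CPM used a prior count of 2. All tests were two-sided.

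Before the data were examined, 49 gene lists were fixed for lung cell types, signalling pathways, cell states, other tissues and blood, RNA quality and sex-linked genes; 791 of their 900 symbols were found, and 46 lists had the minimum of 5 tested members. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01 on voom values, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives: with an estimated correlation 0 list calls held in any of the 7 comparisons. Gene calls are given over all genes tested and adjusted over the list alone.

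The groups, the tests, the lists, the other settings to be tried and the rule for named genes were also set before the data were examined. The rule took the 10 largest rises and 10 largest falls over both sexes among genes with adjusted p under 0.05, a mean of at least 1 CPM and all mutant libraries on one side, which named 0 genes. It also took up to 4 members of each list with the smallest p, Tgfbr1 and 5 sex-linked genes, the 5 largest rises and falls in each sex among called genes of at least 1 CPM with both libraries on the same side, and up to 10 called genes with the smallest p (5 where none was called) in the interaction and the sex effects, passing over unnamed predicted genes. Of the genes taken by this rule, 1 is not reported here. Genes outside it were chosen after their values were seen, also where this is not repeated beside them.

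Groups share replicate numbers 1 and 2 in the labels, which do not say what the number marks. Whether same-numbered libraries deviate together was checked before the calls were compared: over 12793 genes with a mean log2 CPM of at least 2, the correlation across genes of the deviations was 0.180 to 0.626 in the 6 pairs of groups, all above 0.1. The lowest correlation, 0.180, was between control males and mutant males, the groups compared for the genotype effect in males. The next lowest was 0.392, between control males and mutant females. The pairing rule was thus met and blocked values are given beside results that they change. That check rests on the data, since the 4 groups of 2 can be numbered in 8 ways up to mirror image and 1 of these aligns all of them by chance.

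Settings set in advance as alternatives were DESeq2 size factors in edgeR, DESeq2 1.42.0, limma-voom, no filter on low counts, at least 1 CPM in 2 libraries, leaving out each library in turn, and the replicate block. Others set in advance were a size threshold of 1 on the log2 scale, the authors' deposited comparison, only the 4 libraries compared, genotype alone, 4 group means, autosomal genes without the blood, muscle and cartilage lists, an estimated correlation, and fry. Settings chosen after seeing the data were the likelihood ratio test, that test and DESeq2 with the replicate block, a score of each library on the axis that parts the libraries of a group as a covariate, the likelihood ratio test with 1 residual factor, and leaving out each library with the block.

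The fits were tested on simulated data with 18164 genes, of which 200 were changed. Simulated genes varied independently of one another, and each had a shift between replicate numbers that was the same in all groups. For the genotype effect over both sexes, 19.4%, 79.1% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold were recovered with 0 false calls of 131, and with the replicate block 68.7%, 92.5% and 100% with 12 false calls of 186. For the genotype effect in males these were 0%, 8.96% and 75.8% with 0 false calls of 56, and with the block 28.4%, 70.1% and 92.4% with 12 false calls of 139. Correlations across libraries and permutation tests used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures matplotlib 3.10.9. Reads, alignments and any other tables of the study were not analysed here.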

Results

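RNA was measured by sequencing in whole mouse lungs at E17.5, late in gestation, with the oesophagus, trachea and bronchi removed. The mutant lungs carried a constitutively active TGF-β receptor 1, the kinase receptor that passes TGF-β signals to SMAD proteins, in the lung epithelium. There were 4 groups of 2 libraries each: control females, control males, mutant females and mutant males. Reads counted in genes came to 17561012 and 17841733 in control females 1 and 2, and 18421167 and 17743320 in control males 1 and 2. They came to 18606131 and 18652245 in mutant females 1 and 2, and 18564655 and 20243205 in mutant males 1 and 2. Mitochondrially encoded genes held 1.81% to 2.48% of these reads, and the 10 most abundant genes 4.16% to 4.75%. Libraries of 1 group had a Spearman correlation of 0.988 to 0.991 across genes, which are not independent replicates. Their counts differed by 14.6 to 21.2 times the sampling variance, so each was counted as a separate sample. The labels do not state that the libraries came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

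The receptor gene was looked at first. Tgfbr1 (ENSMUSG00000007613, chromosome 4, 47353222 to 47414931 on the plus strand, GRCm38) was at 88.6 and 98.6 CPM (reads scaled to library size) in the control females, 83.6 and 79.7 in the control males, 80.5 and 92.3 in the mutant females and 82.5 and 95.9 in the mutant males. Its mean was 87.6 ± 8.21 CPM in controls and 87.8 ± 7.45 in mutants (SD, n = 4 each). The log2 difference was 0.01 ± 0.09 (SE; edgeR quasi-likelihood adjusted p = 0.996), so the gene does not check the genotype labels. Whether reads of the introduced receptor count under this gene is not given in the sources used here. Xist, the RNA that silences 1 X chromosome in females, was at 1564 ± 14.8 CPM in control females and 1619 ± 283 in mutant females, against 2.97 ± 0.521 in control males and 3.38 ± 0.0574 in mutant males (SD, n = 2 each). Uty, on the Y chromosome, had 0 reads in the 4 female libraries and 3822 reads in the 4 male libraries, at least 1231-fold higher in males against a floor of 3 counts over the female libraries (0.0413 CPM). All 8 libraries thus matched their sex labels. Floors and intervals of read ratios cover counting error only. How reads were assigned by strand is not given in the sources used here, so reads of Xist and of its antisense partner Tsix may not be told apart.

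The first comparison asked how the active receptor changed the embryonic lung over both sexes. Airway and alveolar lists were lower in mutants, through the males. The mean score per library (log2 CPM centred on each gene's mean) was not lower in mutant than in control females in any of these 4 lists. An exact permutation of that score over libraries, mutant against control, gave p = 0.114 for ciliated, 0.143 for club, 0.171 for type 1 and 0.343 for type 2 alveolar genes. The ciliated cell list had a median log2 change of -0.43 with 22 of its 24 members negative, and the club cell list -1.04 with 15 of 19 negative. The type 1 alveolar list stood at -0.51 with 19 of 24 negative, and the type 2 alveolar list at -0.31 with 26 of 27 negative. These 4 lists fell in limma's camera test with a preset correlation (adjusted p = 3.76e-10, 4.74e-06, 3.26e-06 and 0.000183), and each had an adjusted p = 0.684 with an estimated correlation. Without 1 library their medians ran from -0.69 to -0.31 (ciliated), -1.32 to -0.70 (club), -0.75 to -0.27 (type 1) and -0.51 to -0.08 (type 2). The largest separations of mutants from controls were upward. Krt17 (ENSMUSG00000035557), a keratin of basal and stressed epithelia, went from 3, 2, 1 and 2 reads in the control libraries to 52, 105, 60 and 208 in the mutant libraries. Cym (ENSMUSG00000046213), the milk-clotting protease of the stomach, was at 8.58 ± 3.91 CPM in controls and 108 ± 39.9 in mutants (SD, n = 4 each). Apob (ENSMUSG00000020609), the structural protein of lipoprotein particles, was at 0.0701 ± 0.0699 and 2.44 ± 1.74 CPM. These 3 genes were chosen after their values were seen. They lie on chromosome 11 (100256217 to 100261029, minus strand), chromosome 3 (107211293 to 107221732, minus strand) and chromosome 12 (7977648 to 8016835, plus strand) of GRCm38.

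The log2 change over both sexes was 5.50 ± 0.58 for Krt17, 3.71 ± 0.38 for Cym and 5.01 ± 0.80 for Apob (SE, n = 4 against 4), with edgeR quasi-likelihood adjusted p = 0.0518, 0.0518 and 0.283. Krt17 went from 8 to 425 reads in all, a ratio of 49.6 per read sequenced (95% interval 24.9 to 116), and Apob went from 5 to 184 reads, a ratio of 34.3 (14.5 to 107). With the replicate number as a block all 3 rose (adjusted p = 0.00263, 0.0325 and 0.00263). Over 23 alternatives the adjusted p ran from 3.66e-43 to 0.677 for Krt17, from 1.35e-23 to 0.677 for Cym and from 1.54e-33 to 1.00 for Apob. It was highest for all 3 without control male 2. Krt17 passed without mutant female 1 (0.0488), mutant male 1 (0.0293) or mutant male 2 (0.0184). Cym passed without mutant male 1 (0.0293) or mutant male 2 (0.0282), and Apob in no fit without 1 library. Krt17 belongs to the keratin family, and how reads shared between copies were counted is not given in the sources used here.

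**Figure D1:**
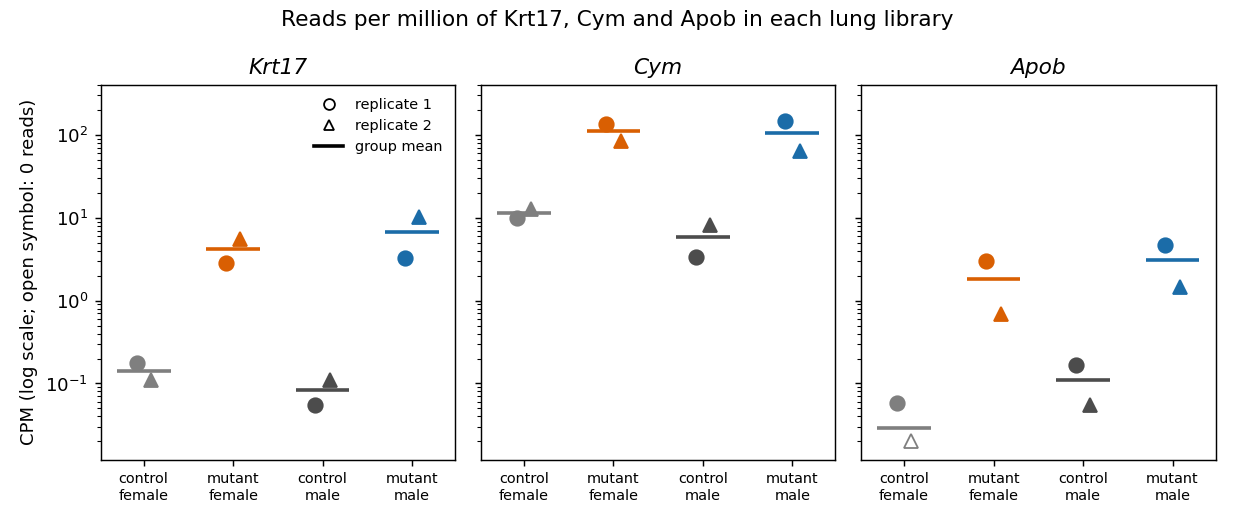
CPM (log axis) of Krt17, Cym and Apob in each of the 8 libraries, by group; circles and triangles are libraries 1 and 2 of a group, horizontal lines are group means, and the open triangle near the bottom of the axis is a library with 0 reads. All 4 mutant libraries lie above all 4 control libraries for each gene, with Cym averaging 8.58 CPM in controls and 108 CPM in mutants.

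Among single genes of the fixed lists, values over both sexes were -2.93 ± 0.88 on the log2 scale for Aqp5, the water channel of type 1 alveolar cells (adjusted p = 0.669), and -2.73 ± 0.70 for Krt15 (0.635). Krt19 stood at -0.91 (0.656), Krt8 at -0.50 (0.635) and the tight junction gene Cldn4 at -0.70 ± 0.13 (0.505). Foxj1, the master regulator of motile cilia, stood at -0.77 and Ccno, needed for multiciliated cells, at -0.71. None of these passed the edgeR quasi-likelihood test. Of the TGF-β pathway itself, Mmp2 stood at 0.29 ± 0.08, Ski at 0.40 ± 0.11, Skil at 0.27 and Tgfb2 at -0.32, none of them called. Timp3, a target with one of the smallest p that is also in the type 1 alveolar list, went the other way from Mmp2, Ski and Skil. In the authors' deposited comparison Timp3 had a log2 change of -0.58 (FDR 7.83e-05). The list of TGF-β and SMAD targets had a median of 0.09 with 20 of 28 members positive (camera adjusted p = 0.0708; 0.0361 with the replicate block, and adjusted p = 0.630 with the block and an estimated correlation). TGF-β ligands and receptors (median 0.01, adjusted p = 0.751), epithelial to mesenchymal transition genes (0.14, 0.123) and extracellular matrix genes (-0.03, 0.686) did not pass. Ribosomal protein genes, fixed as a sign of RNA quality, rose with a median of 0.16 and 36 of 36 positive (adjusted p = 1.71e-09; 0.684 with an estimated correlation).

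The edgeR quasi-likelihood test with a term for sex called 0 of 18164 genes, with 1061 at an unadjusted p under 0.05 where chance gives 908. DESeq2 called 88 genes, limma-voom 0, edgeR's likelihood ratio test 79 and the quasi-likelihood test with the replicate block 3. All 4 mutant libraries lay above all 4 controls in 300 genes and below them in 316, where chance separates 2.86% of genes, or 259 each way. Over the lists, 15 of 46 passed camera with the preset correlation, 4 up and 11 down, and none with an estimated correlation. The fall of the type 2 alveolar list was lost without control male 1 (adjusted p = 0.546) or mutant male 2 (0.0740). A rise of the macrophage list (median 0.17, adjusted p = 0.000596, 0.684 with an estimated correlation) was lost without control male 2 (0.120) or mutant female 1 (0.0601).

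In males, the comparison of mutant with control lungs showed lower levels of genes that mark differentiated airway and alveolar cells. Scgb1a1, the main secretory protein of club cells, fell from 71.7 ± 47.0 to 2.18 ± 1.71 CPM, Aqp5 from 35.4 ± 25.5 to 0.812 ± 0.527 CPM, and Krt15, a keratin of basal cells, from 38.7 ± 17.4 to 1.32 ± 0.344 CPM (SD, n = 2 each). On the log2 scale these were -5.06 ± 0.79, -5.46 ± 0.77 and -4.86 ± 0.54 (SE; edgeR quasi-likelihood adjusted p = 0.0322, 0.0286 and 0.0198). The 5 largest falls by the fixed rule also held Rasgrf2 (-4.63 ± 0.84, adjusted p = 0.0433) and Gjb6, a gap junction gene (-3.97 ± 0.64, 0.0327). Among the 5 largest rises, Krt17 (6.22 ± 0.86, adjusted p = 0.0282) went from 3 to 268 reads, a ratio of 82.4 with a 95% interval of 27.9 to 402. Cym (4.17 ± 0.51, 0.0270) rose from 5.82 ± 3.43 to 105 ± 58.2 CPM. The others were Ntm, a neuronal adhesion gene (2.91 ± 0.39, 0.0282), the secreted protease gene Adamts18 (2.44 ± 0.41, 0.0356) and Tub (2.42 ± 0.42, 0.0370). Krt15 and Krt17 are both members of the basal cell list, which had a median of -0.12 (camera adjusted p = 0.528).

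By cell type, the club cell list fell in mutant males with a median log2 change of -1.86. Over all genes 7 of its 19 members fell and 0 rose, and adjusted over the list alone 14 fell and 1 rose. Its members Cbr2 (-3.93 ± 0.48), Cyp2f2 (-2.19 ± 0.28) and Scgb3a2 (-1.91 ± 0.30) fell, as did Hp (-2.66 ± 0.36). The type 1 alveolar list had a median of -1.11, with 7 of 24 members falling over all genes, and 17 falling and 1 rising adjusted over the list alone. Clic5 (-2.28 ± 0.31), Gprc5a (-1.70 ± 0.25) and Lmo7 (-1.44 ± 0.22) fell, and Sec14l3 (-1.83), which the club list also holds, fell too, while Ager, the receptor that marks type 1 cells, stood at -1.48 (adjusted p = 0.0762). Type 2 alveolar genes had a median of -0.84, with 2 of 27 falling over all genes and 17 adjusted over the list alone, the former being Chia1 (-3.76 ± 0.66) and Sfta2 (-0.87 ± 0.16). Ciliated cell genes had a median of -0.95, with 6 of 24 falling over all genes and 21 adjusted over the list alone. Foxj1 fell by 1.35 ± 0.17 on the log2 scale, and the dynein arm genes Dnah5 (-1.28 ± 0.24) and Dnah9 (-1.18 ± 0.22) fell with it. Cyp2f2, Clic5, Sec14l3, Ager, Dnah5 and Dnah9 were chosen after their values were seen. The camera adjusted p was 1.20e-08 for club, 4.98e-10 for type 1, 1.81e-08 for type 2 and 8.58e-15 for ciliated genes, and with an estimated correlation the adjusted p = 0.471, 0.562, 0.562 and 0.562. Without 1 library the medians ran from -2.09 to -1.52, -1.34 to -0.75, -1.16 to -0.47 and -1.07 to -0.86 in the same order. With the replicate block 14 club, 18 type 1, 21 type 2 and 22 ciliated genes fell over all genes, and 1 type 1 gene rose.

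**Figure D2:**
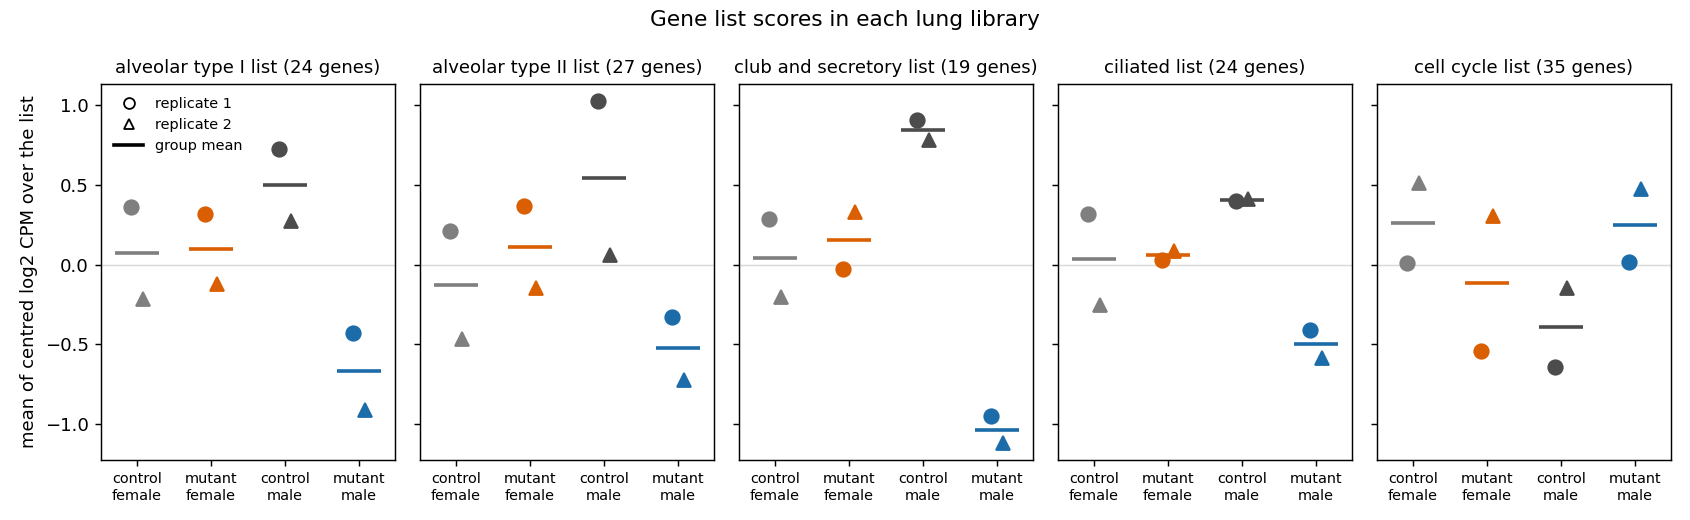
Score of each library (mean over a list's genes of log2 CPM minus the gene's mean over the 8 libraries, log2 units) for the type 1 alveolar, type 2 alveolar, club, ciliated and cell cycle lists; circles and triangles are libraries 1 and 2 of a group and horizontal lines are group means. In the type 1 alveolar list mutant males 1 and 2 lie at -0.43 and -0.91, control males at 0.72 and 0.27, control females at 0.36 and -0.21, and mutant females at 0.32 and -0.12.

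Genes used by dividing and by immature distal cells lay higher in mutant males. The cell cycle list had a median of 0.68 with 35 of 35 members positive (camera adjusted p = 2.55e-09; 0.578 with an estimated correlation). No single member passed (0 over all genes, 0 adjusted over the list alone), while 33 rose with the replicate block. Cdk1, the mitotic kinase, chosen after its values were seen, stood at 0.72 (edgeR quasi-likelihood adjusted p = 0.133). Cartilage genes, fixed as a sign of trachea, bronchi or chest wall in the sample, rose too (median 1.14, camera adjusted p = 0.00187, 0.562 with an estimated correlation). Of 9 members, Col9a1 (1.77 ± 0.25) and Col9a3 (1.87 ± 0.34) rose over all genes, and 5 rose and 1 fell adjusted over the list alone. Distal tip progenitor genes rose (median 0.21, adjusted p = 0.0310, 0.562 with an estimated correlation). Mycn rose by 1.40 ± 0.19, and Etv4 (1.29, 0.0558) and Sox9 (0.88, 0.0578) lay just outside the threshold. Fgfr2, also a member of the distal tip list, went the other way. It was at 512 and 498 CPM in control males 1 and 2, and 388 and 349 in mutant males 1 and 2. The distal tip list no longer passed without control male 1 or mutant male 1. Ion and fluid transport genes, whose called member was Aqp5, fell (median -0.77, adjusted p = 6.50e-08, 0.562 with an estimated correlation; 1 of 16 over all genes and 7 adjusted over the list alone). Epithelial junction genes fell (-0.32, 2.38e-05, 0.562 with an estimated correlation), with 3 of 24 falling over all genes, and 10 falling and 2 rising adjusted over the list alone. Krt8 stood at -0.78 ± 0.12, Krt19 at -1.56 ± 0.20 and Cldn4 at -0.94 ± 0.15, all called. Smooth muscle and myofibroblast genes fell (-0.28, 0.000327, 0.471 with an estimated correlation; 1 of 15, and 3 adjusted over the list alone), the called member being Myh11 (-0.72 ± 0.11). Eln, the gene of elastin, fell by 1.54 ± 0.22, Wnt5a by 0.66 ± 0.11 and Fgf18 by 1.11 ± 0.18. The TGF-β and SMAD target list had a median of 0.05 (adjusted p = 0.979). Ribosomal protein genes rose here too (0.29, 1.81e-08, 0.578 with an estimated correlation), beside each of these lists. Early response and heat shock genes, a sign of handling, fell (median -0.39, camera adjusted p = 0.0164, 0.562 with an estimated correlation) and were lost without control male 1 (0.154).

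The edgeR quasi-likelihood test called 235 of 18164 genes between mutant and control males, 47 higher and 188 lower, and 3502 had an unadjusted p under 0.05. With the replicate number as a block 3038 passed (1326 higher, 1712 lower). Same-numbered control and mutant males deviated together least of all pairs of groups (r = 0.180 across genes), so the block is least backed here. DESeq2 called 855 and limma-voom 183. Of the 235, 4 were still called without control male 1, 86 without control male 2 and 0 without mutant male 1 or mutant male 2. The median absolute log2 change of the 235 was 1.24, 1.32, 1.38 and 1.24 in these 4 fits against 1.30 with all libraries. With the replicate block 235 stayed called in each of the 8 fits without 1 library, and these genes were picked for their call. Without control male 1, control male 2, mutant male 1 and mutant male 2, Krt17 had adjusted p = 0.171, 0.0781, 0.0549 and 0.141, and Cym 0.15, 0.0344, 0.0834 and 0.0530. Over 27 alternatives the range was 4.34e-31 to 0.171 for Krt17 and 9.02e-19 to 0.15 for Cym. Of the 46 lists 20 passed, 0 with an estimated correlation. The club, alveolar, ciliated, cell cycle, cartilage, ion transport, epithelial junction, smooth muscle and ribosomal lists passed in each of the 8 fits that left out 1 library.

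In females, the same comparison called a set of higher genes only in some alternative fits, such as that with the replicate block. It gave little difference in the alveolar and airway lists. Cym was at 11.3 ± 1.91 CPM in control females and 110 ± 37.0 in mutant females (SD, n = 2 each), a log2 difference of 3.27 ± 0.48 (SE). Krt17 stood at 4.82 ± 0.82, from 5 to 157 reads, a ratio of 29.7 (95% interval 12.4 to 92.6). Apob went from 1 and 0 reads to 55 and 13, and Nt5e, the ectoenzyme that makes adenosine, stood at 2.06 ± 0.42. Each had an edgeR quasi-likelihood adjusted p = 1, and each rose with the replicate block (adjusted p = 0.00568 for Cym, 0.00270 for Krt17, 0.00568 for Apob and 0.00270 for Nt5e). Over 19 alternatives the adjusted p ran from 1.53e-11 to 1 for Cym, 1.02e-18 to 1 for Krt17, 2.39e-11 to 1 for Apob and 3.85e-16 to 1 for Nt5e. With the block Igfbp7 (1.12), Fbln5, a gene of elastic fibres (0.81), Wipf3 (1.85), Slc39a2 (2.78), Batf (1.56) and Cd55 (0.67), which shares sequence with Cd55b, also rose. These log2 values are from the fit without the block. Apob, Nt5e, Igfbp7, Wipf3, Slc39a2, Batf and Cd55 were chosen after their values were seen.

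The list of TGF-β and SMAD targets rose in mutant females with a median of 0.20 and 20 of 28 members positive (camera adjusted p = 0.000465, 0.963 with an estimated correlation), and was lost without control female 2 (0.197) or mutant female 1 (0.655). Cell cycle genes fell (median -0.37, 35 of 35 negative, adjusted p = 2.87e-12, 0.963 with an estimated correlation), lost without control female 2 (0.115) or mutant female 1 (0.638, median 0.03). Cardiac muscle genes, which mark another tissue, rose beside them (0.69, 12 of 12 positive, 0.000465, 0.963 with an estimated correlation), lost without control female 1 (0.951, median -0.10). Macrophage and monocyte genes rose (0.21, 0.00815, 0.963 with an estimated correlation), lost without control female 2 (0.443) or mutant female 1 (0.511). Medians were -0.02 for type 1 alveolar (adjusted p = 0.689), -0.05 for club (0.889) and 0.00 for ciliated genes (0.777), and 0.20 for type 2 alveolar genes (0.0553; 3.97e-07 with the replicate block, and adjusted p = 0.855 with the block and an estimated correlation). In these lists 0 members passed, over all genes or adjusted over the list alone. With the replicate block and adjusted over the list alone, 33 cell cycle genes fell and 5 TGF-β and SMAD targets rose. Over all genes the edgeR quasi-likelihood test called 0 genes in females, and 290 had an unadjusted p under 0.05 where chance gives 908. DESeq2 called 6, limma-voom 0, and the quasi-likelihood test with the replicate block 14, all higher.

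The series asks about a disadvantage of males, so whether the genotype effect differed between the sexes was tested directly as an interaction. The genotype effect was lower in males than in females for type 1 alveolar (median difference -1.15), type 2 alveolar (-0.95), club (-1.62) and ciliated genes (-0.99), and higher for cell cycle (1.05) and cartilage genes (1.21). The cartilage list had been fixed as a sign of trachea, bronchi or chest wall in the sample. The camera adjusted p for these 6 lists was 3.48e-10, 1.17e-08, 2.96e-08, 4.51e-13, 1.40e-14 and 0.000562, and each passed in all 8 fits without 1 library, where the medians ran from -1.43 to -0.87, -1.33 to -0.62, -1.98 to -1.20, -1.28 to -0.66, 0.64 to 1.46 and 0.67 to 1.81. Over all 22 lists that passed, 8 up and 14 down, the adjusted p = 0.559 to 0.706 with an estimated correlation. Adjusted over the list alone, 14 ciliated, 14 type 1, 14 type 2 and 10 club genes were lower and 1 type 1 gene was higher, and over all genes 0 passed. With the replicate block 33 of 35 cell cycle genes were higher, and 19 type 1, 20 type 2, 12 ciliated and 12 club genes lower, over all genes. Among the genes with the smallest p were Epha4, a receptor for ephrins (0.92 ± 0.13), Col9a1 (2.38 ± 0.34), Chad, a cartilage matrix gene (-2.21 ± 0.36), and the protease gene Adamdec1 (1.55 ± 0.25), each with edgeR quasi-likelihood adjusted p = 0.317. Adamdec1 averaged 8.75 CPM in control females, 9.05 in control males, 13.9 in mutant females and 42.2 in mutant males.

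**Figure D3:**
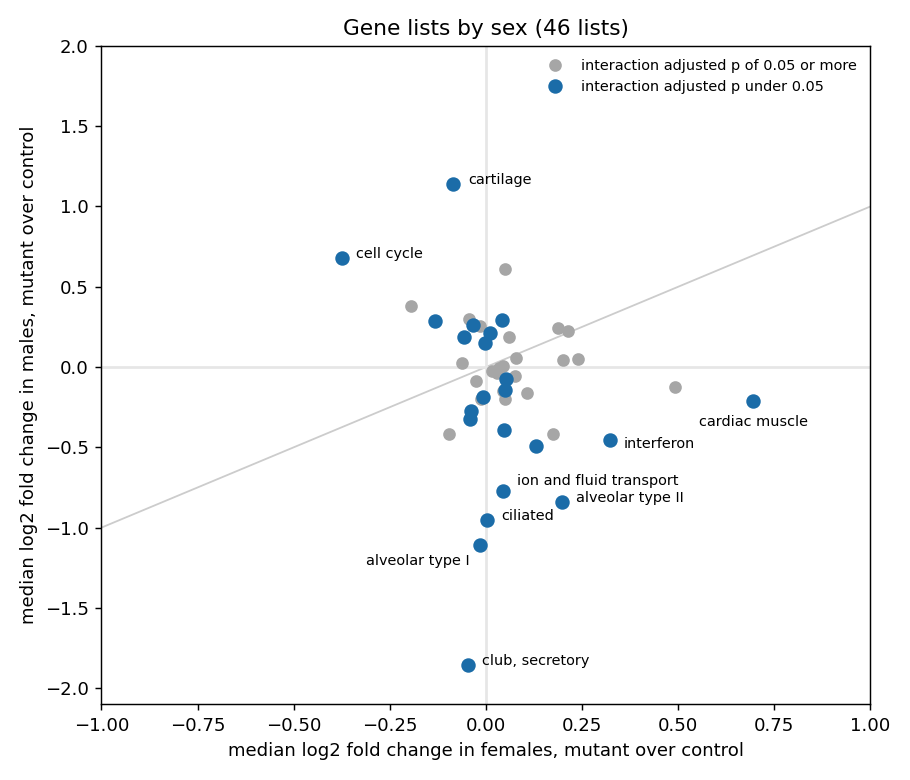
Median log2 change between mutant and control of each fixed list in females (horizontal axis) and in males (vertical axis), log2 units; each point is 1 of 46 lists, blue where the interaction passed camera with a preset correlation (22 lists, 0 with an estimated one), and the grey diagonal marks equal change in both sexes. The club cell list lies at -0.05 in females and -1.86 in males, and the cell cycle list at -0.37 and 0.68.

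Over all genes the interaction gave 0 calls in the edgeR quasi-likelihood test, with 2266 genes at an unadjusted p under 0.05. There were 188 calls by DESeq2, 196 by the likelihood ratio test, 0 by limma-voom, and 1695 with the replicate block (712 higher, 983 lower). With the block Epha4 had adjusted p = 0.000840, Col9a1 0.000198, Chad 0.00261 and Adamdec1 0.00187. Over 26 alternatives the range was 4.01e-09 to 0.760 for Epha4 and 1.95e-16 to 0.760 for Col9a1. It was 3.59e-07 to 0.796 for Chad and 5.58e-08 to 0.796 for Adamdec1. Krt17 (1.40, adjusted p = 0.731) and Cym (0.90, 0.564), chosen after their values were seen, did not pass. Over 26 alternatives the range was 0.312 to 0.953 for Krt17 and 0.00547 to 0.975 for Cym, which passed in 1 of them (without control male 2, with the replicate block), so no stable sex difference was shown for them. The TGF-β and SMAD target list, which passed in females and not in males, had an interaction median of -0.16 (camera adjusted p = 0.145; 0.0198 with the replicate block, and adjusted p = 0.622 with the block and an estimated correlation). Over all genes the log2 changes of females and males had r = -0.0472, a descriptive value since genes are not independent. Of the 235 genes called in males, 164 had the same sign in females and 226 had an unadjusted interaction p under 0.05, while 35.2% of the 3038 male calls with the replicate block had the same sign in females. The median absolute log2 change of the 235 was 1.30 in males and 0.17 in females, and these genes were picked for their change in males.

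The sexes were compared within each genotype for their baseline difference. Control males had higher levels than control females of the type 2 alveolar (median 0.53), club (0.60), type 1 alveolar (0.43), ion transport (0.49) and ciliated lists (0.33), and lower levels of cell cycle genes (-0.67). The camera adjusted p was 3.91e-07 for type 2, 0.000139 for club, 0.000198 for type 1, 0.000286 for ion transport, 1.42e-06 for ciliated and 2.32e-15 for cell cycle genes, and the adjusted p = 0.803 for each with an estimated correlation. Without 1 library the medians ran from 0.14 to 0.88 (type 2), 0.29 to 0.96 (club), 0.13 to 0.69 (type 1), 0.07 to 0.71 (ion transport), 0.09 to 0.63 (ciliated) and -0.91 to -0.43 (cell cycle). Without control male 1 the type 2 (0.240) and type 1 (0.147) lists were lost, and without control female 2 the type 1 (0.358), ciliated (0.214) and ion transport (0.185) lists. The 13 lists that passed camera in controls also held ribosomal protein genes, a sign of RNA quality, and cartilage genes, both lower in males. They held cardiac muscle, interferon, hypoxia and glucocorticoid genes as well, all higher in males. The 23 lists in mutants also held ribosomal protein, erythroid and cartilage genes, higher in males, and early response and cardiac muscle genes, lower in males. In mutants the order was the other way: ciliated (-0.61), type 1 alveolar (-0.69), club (-1.02) and type 2 alveolar genes (-0.50) were lower in males and cell cycle genes higher (0.37). Their camera adjusted p was 3.17e-15, 1.52e-13, 2.26e-09, 8.41e-07 and 2.34e-07, and the adjusted p = 0.489, 0.489, 0.280, 0.563 and 0.607 with an estimated correlation. Without 1 library the medians ran from -0.68 to -0.54, -0.98 to -0.38, -1.31 to -0.75, -0.69 to -0.23 and -0.04 to 0.77 in the same order. The cell cycle list was lost without mutant female 1 (0.530, median -0.04) or mutant male 2 (0.0890).

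In the edgeR quasi-likelihood test without the replicate block, most of the named genes called between the sexes lay on the sex chromosomes. With the block the calls were 704 in controls, 329 in mutants and 7 over both genotypes, and DESeq2 called 80 in mutants. Xist was lower in males by a log2 difference of -9.04 ± 0.21 in controls and -8.90 ± 0.21 in mutants (edgeR quasi-likelihood adjusted p = 5.08e-07 and 5.20e-07). The Y-linked genes Uty (49.6 CPM in control and 52.2 in mutant males), Kdm5d (78.9 and 88.4), Ddx3y (107 and 96.7) and Eif2s3y (87.8 and 91.1) were called in both genotypes. Eif2s3x, which escapes X inactivation, was lower in control males (-0.88 ± 0.10, adjusted p = 0.0284) and lost its call without any 1 of the 8 libraries (adjusted p = 0.0561 to 0.437). Kdm6a, another escape gene, was lower in males over both genotypes (-0.59 ± 0.06, 0.0150) and lost its call without each library but mutant female 1 (0.0713 to 0.157). Adamdec1 was higher in mutant males than in mutant females (1.60 ± 0.18, 0.0272) and lost its call without mutant female 1 (0.144), mutant female 2 (0.333), mutant male 1 (0.253) or mutant male 2 (0.186).

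Without the block each of the 3 sex comparisons called 7 genes, the remaining call in each being an unnamed predicted gene. The list of X-linked escape genes was lower in control males (median -0.38, camera adjusted p = 2.57e-10, 0.721 with an estimated correlation; 2 of 13 over all genes, 7 adjusted over the list alone) and in males over both genotypes (-0.24, 3.27e-19, 0.337 with an estimated correlation; 2 over all genes, 6 adjusted over the list alone). Over both genotypes lipid and cholesterol genes were also lower in males (-0.12, 1.12e-05, 0.955 with an estimated correlation). Smooth muscle genes were lower (-0.11, 0.000920), lost without mutant female 1 (0.0640). Cell cycle genes were lower (-0.15, 0.00511), lost without control female 2 (0.259), control male 1 (0.513) or mutant female 2 (0.174), and 0 of these lists held with an estimated correlation.

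The authors' deposited table of their own comparison of mutant with control lungs listed 775 of 19150 genes at a false discovery rate under 0.05, 232 higher and 543 lower in mutants. In the authors' deposited table Krt17 had a log2 change of 5.51 (FDR 3.66e-43), Cym 3.70 (1.35e-23) and Apob 5.08 (7.13e-13). That authors' deposited table called 12 of 24 type 1 alveolar, 8 of 27 type 2 alveolar, 8 of 19 club and 8 of 24 ciliated genes, all lower, and 4 of 16 distal tip progenitor genes and 4 of 10 cartilage genes, all higher. Of its TGF-β and SMAD targets 4 were higher and 2 lower of 29 in the authors' deposited table. Among its 775 calls, 767 were tested here, all with the same sign in the edgeR quasi-likelihood test over both sexes, and 526 had an unadjusted p under 0.05 there.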

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

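The tests of a smaller epithelial share, of the male calls kept without 1 library, of a hidden factor, of the likelihood ratio test alone, of liver tissue, of the axis between replicate numbers for Krt17, Cym and Apob, and of other splits for the count of 0 genes were chosen only after their results were seen, as were the fits with an axis score or a residual factor. The results listed in this part are gene lists whose genotype effect differed between the sexes by the interaction test (camera with a preset correlation); with an estimated correlation the adjusted p was 0.559 to 0.706 for all of them, so 0 of the 22 held. Single samples standing apart from their group were not looked for, since each group had 2 libraries.

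The first pattern is the fall of alveolar, club and ciliated markers in mutant males, with an interaction median of -1.15 for type 1 alveolar (-0.02 in females, -1.11 in males), -0.95 for type 2 alveolar (0.20 and -0.84), -1.62 for club (-0.05 and -1.86) and -0.99 for ciliated genes (0.00 and -0.95). A smaller share of epithelium stays open. The 92 type markers lay -0.70 on the log2 scale from the 24 junction genes shared by epithelial cells (medians of edgeR log2 changes -1.01 and -0.31). A permutation test gave p = 8.00e-05 over 100000 divisions of genes, which are not independent. This gap cannot decide it, since the type lists were picked for their fall. Junction genes may also be expressed outside the epithelium, and the mesothelium list also holds Krt19. The 16 distal tip genes had a median of 0.20 (the list tests, on voom values, give -0.32 for junction and 0.21 for distal tip genes). Lung epithelial transcription factors passed camera as lower in mutant males, not with an estimated correlation. Their median was -0.28 to -0.13 without 1 library. Different maturity along the axis that parts replicate 1 from replicate 2 stays open. With the axis score as a covariate 235 of the 235 male calls stayed called (median absolute log2 change 1.30 before and 1.20 after). These genes were picked for their call and the score was computed from the same counts, so this cannot decide it. Over genes the axis had r = -0.392 with the genotype effect in males and -0.462 with the interaction, descriptive values since genes are not independent. Whether 1 library decides the male calls stays open: without control males 1 and 2 and mutant males 1 and 2 in turn 4, 86, 0 and 0 of the 235 were kept, while their median absolute log2 change (1.24, 1.32, 1.38 and 1.24, against 1.30) stayed near and 235 were kept with the replicate block in each of 8 such fits, but genes picked for their call cannot decide it. Other differences between these embryos or litters, the high values of the control males that enter the contrast, and a delayed or diverted differentiation of the epithelium in mutant males may each contribute, and the last is a hypothesis found and tested on the same data.

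The second pattern is that the authors' deposited comparison called 775 genes where the edgeR quasi-likelihood test called 0. The choice of the likelihood ratio test alone is argued against, since with the same terms it called 79 of the 18164 filtered genes. It called 160 of all 19150 genes with upper-quartile in place of TMM normalization and another estimate of the spread per gene. The fits below on the 19150 genes share these settings. A candidate explanation is a term for a hidden factor in the deposited comparison: with 1 residual factor and genotype the rank correlation of p over genes with the deposited p was 0.990 and 915 genes were called, 701 of them shared, against 0.946 to 0.960 and 136 to 257 calls with genotype, sex and replicate number in any of the 4 combinations tried, all on the 19150 genes. That residual factor followed the axis between the libraries of a group (r = 0.940 over the 8 libraries, a descriptive value since both were computed from the same counts). Whether the authors used such a term is not given in the sources used here.

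The third pattern is the rise of Krt17, Cym and Apob in all mutant libraries. Stomach tissue that would raise its markers together is argued against, since the 7 tested of 17 stomach markers had a median log2 change of -0.15. Of the 3 with an unadjusted p under 0.05 Ctse was higher (1.21) and Pgc (-0.99) and Ghrl (-0.82) lower. Ctse lay above all controls in all mutants (lowest mutant 1.27, highest control 1.11 CPM). Muc5ac, another of these markers, is also in the club list, so the set is not read from stomach alone. A small share of stomach is not excluded. Liver tissue stays open for Apob: the 4 tested of 15 liver markers had a median log2 change of 0.19, with Trf (-0.36) and Itih2 (-0.28) lower and the untested Apoa2 higher by 0.0166 CPM, but Rbp4 (0.74, higher by 2.69 CPM) lay above all controls in all mutants, and Alb was higher by 0.865 CPM (SE 0.337) where Apob was by 2.37 (SE 0.872). On the axis that parts replicate 1 from replicate 2, controls (-1.21 to 1.24) and mutants (-1.22 to 1.16) overlapped, so a place on it alone does not part the genotypes. With the axis score 3 of the 3 genes were called (log2 5.25, 3.68 and 5.67, edgeR quasi-likelihood adjusted p = 0.000205, 0.00133 and 0.000146). These calls decide nothing further, since the genes were chosen for their rise and the score came from the same counts. Over 23 alternatives the adjusted p ran from 3.66e-43 to 0.677 for Krt17, 1.35e-23 to 0.677 for Cym and 1.54e-33 to 1.00 for Apob. Embryo differences off this axis were not tested. An effect of the receptor, or of the genetic background that came with it, may account for the rise and was not told apart here.

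The other lists differed between the sexes as follows, each as the interaction median with the median in females and in males. Cell cycle genes were at 1.05 (-0.37 and 0.68; camera adjusted p = 1.40e-14). Ion and fluid transport genes were at -0.93 (0.04 and -0.77; 2.18e-07). Ribosomal protein genes were at 0.24 (0.04 and 0.29; 4.37e-05), lost without control female 1 (0.108) or mutant male 1 (0.154). Epithelial junction genes were at -0.47 (-0.04 and -0.32; 0.000439). Cartilage genes, a sign of trachea, bronchi or chest wall in the sample, were at 1.21 (-0.08 and 1.14, camera adjusted p = 0.000562). Glucocorticoid response genes were at -0.64 (0.13 and -0.49; 0.00133).

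Of the lists lost without single libraries, smooth muscle genes were at -0.33 (-0.04 and -0.28; 0.00602; lost without mutant male 1 at 0.0636). Cardiac muscle genes were at -0.98 (0.69 and -0.21; 0.00489; lost without control female 1 at 0.340, control male 2 at 0.0538 or mutant male 1 at 0.164). Fibroblast genes were at -0.14 (0.05 and -0.08; 0.0190; lost without control female 2 at 0.0566, control male 1 at 0.0935 or mutant female 1 at 0.0646). Interferon-stimulated genes were at -0.71 (0.32 and -0.46; 0.0192; lost without control female 2 at 0.502, control male 1 at 0.327 or mutant female 1 at 0.267). Lipid and cholesterol genes were at -0.31 (-0.01 and -0.19; 0.0231; lost without control female 1 at 0.108, control male 1 at 0.247, mutant female 2 at 0.105 or mutant male 1 at 0.201). Early response and heat shock genes, a sign of handling, were at -0.42 (0.05 and -0.39; 0.0261; lost without control male 1 at 0.108, mutant female 1 at 0.110 or mutant male 1 at 0.0601).

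Erythroid genes were at 0.51 (-0.13 and 0.29; 0.0261; lost without control female 2 at 0.287, control male 2 at 0.336, mutant female 2 at 0.242 or mutant male 1 at 0.0636). X-linked escape genes were at 0.16 (-0.06 and 0.19; 0.0261; lost without control female 2 at 0.0566, control male 2 at 0.0799, mutant female 1 at 0.110 or mutant male 2 at 0.0844). Distal tip progenitor genes were at 0.32 (0.01 and 0.21; 0.0370; lost without control female 2 at 0.131, control male 1 at 0.0805, mutant female 2 at 0.0611 or mutant male 1 at 0.175). BMP targets were at 0.23 (-0.03 and 0.26; 0.0381; lost with the replicate block, and without control female 2 at 0.127, control male 1 at 0.0805, mutant female 1 at 0.106, mutant female 2 at 0.0514 or mutant male 1 at 0.154). Endothelial genes were at -0.18 (0.05 and -0.14; 0.0395; lost without control female 1 at 0.0882, control female 2 at 0.0566, control male 1 at 0.0805, mutant female 1 at 0.217 or mutant male 1 at 0.154). Hedgehog pathway genes were at 0.27 (0.00 and 0.15; 0.0488; lost without control female 2 at 0.313, control male 1 at 0.203, mutant female 1 at 0.144 or mutant male 1 at 0.164).

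The 8 libraries were also split in other ways. Every split calls at least 0 genes, so the 0 genes called between mutant and control, reached by 35 of the 35 splits of 4 against 4 (highest other 1758), decide nothing about chance. The splits do not exclude chance for the other counts without the replicate block. For the 1061 genes at an unadjusted p under 0.05, 11 of the 35 splits gave as many (highest other 5037), and for the 15 lists 15 of 35 (highest other 24). With the replicate block 3 genes were called, 2 of the 18 splits with 2 libraries of each replicate number on each side gave as many (highest other 8, the split by sex), and these splits are too few for a share under 0.05. For the 7 genes called between males and females, 2 of the 35 splits gave as many (highest other 1329), and for the 4 lists 35 of 35 (highest other 21). That leaves chance open for the number 7 and not for a gene such as Uty, with 0 reads in the 4 female libraries and 3822 in the 4 male libraries. The split that called 1758 and 1329 genes sets control female 1, both control males and mutant female 1 against the rest, follows the first principal component (37.7% of the variance) and points to a structure of the samples that the groups do not name. The split by replicate number called 0 genes, with 2798 at an unadjusted p under 0.05 and 20 lists. Comparisons of 2 libraries with 2 allow no such count.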

How the results depend on the processing

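The likelihood ratio test, the replicate block joined to it, to DESeq2 or to leaving out a library, the within-group axis score and the residual factor were chosen after seeing the data; the other alternatives were set before the data were examined. Pseudocount alternatives were not run, since counts were deposited. Of the genes run under the alternatives (48 over both sexes, 12 in females, 54 in males, 10 in the interaction, and 7, 6 and 6 between the sexes in controls, in mutants and over both genotypes), 1 changed sign in any fit; most were picked for their values. This was Tgfbr1, whose log2 change over both sexes of 0.01 was -0.0629 to 0.0688 without 1 library, and -0.0013 without control female 1, -0.0069 without control male 1, -0.0326 without control male 2, -0.0075 without mutant female 2 and -0.0629 without mutant male 2. It was -0.0024 in DESeq2 with the replicate block and -0.0271 with the axis score, all within its standard error. Of the 235 male calls 235 stayed called with the block, 230 in DESeq2 and 180 in limma-voom. Calls were sensitive to the test and the terms. Without the block 19.4% of 1.5-fold, 79.1% of 2-fold and 98.5% of 4-fold changes were recovered in the simulated comparison over both sexes, and 0%, 8.96% and 75.8% in males. With the block 12 of 186 and 12 of 139 simulated calls were false. The simulated genes varied independently, while in these libraries 1 shared axis held 48.7% of the within-group variance. The simulated shares thus need not hold here. The count of 0 over both sexes does not exclude changes of 1.5-fold or larger ones. Krt17, from 8 to 425 reads, was itself not called (edgeR quasi-likelihood adjusted p = 0.0518). Low counts limit Krt17 and Apob, with 8 and 5 reads in all 4 controls.

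Over both sexes, where the quasi-likelihood test called 0 genes, DESeq2 size factors gave 2, no filter 2, DESeq2 88 (46 higher, 42 lower), the replicate block 3, genotype alone 3, 4 group means 21, the authors' deposited comparison 775, the likelihood ratio test 79, 160 with the block and 970 with a residual factor, DESeq2 with the block 150 and the axis score 39 (31 higher, 8 lower); limma-voom, at least 1 CPM in 2 libraries, the size threshold and autosomal genes alone gave 0. Without 1 library the count was 0 to 3: 1 without mutant female 1, 2 without mutant male 1 and 3 without mutant male 2. Adding the residual factor took the count of the likelihood ratio test from 79 to 970; the cause of the other shifts was not tested.

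In females the count of 0 became 6 in DESeq2, 14 with the block, 8 by the likelihood ratio test and 87 with its block, 45 in DESeq2 with the block and 7 with the axis score, and stayed 0 without any 1 library. In males 235 became 855 in DESeq2 (199 higher, 656 lower), 3038 with the block, 422 with only the 4 libraries compared, 1096 by the likelihood ratio test and 3614 with its block, 2355 in DESeq2 with the block and 1245 with the axis score. Without 1 library it was 0 to 245: 5 without control male 1, 120 without control male 2 and 0 without either mutant male; with the block it was 2287, 2286, 3525, 2390, 2777, 2762, 1262 and 1736 without control females 1 and 2, control males 1 and 2, mutant females 1 and 2 and mutant males 1 and 2. In the interaction 0 became 188 in DESeq2 (29 higher, 159 lower), 1695 with the block, 196 by the likelihood ratio test and 2315 with its block, 1436 in DESeq2 with the block and 155 with the axis score. Without 1 library it was 0 to 1 (1 without control male 2 and 1 without mutant female 1), and with the block, in the same order of libraries, 777, 623, 3025, 1738, 717, 1383, 973 and 1167. The cause was not tested.

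Between the sexes in controls 7 calls became 704 with the block, 19 by the likelihood ratio test and 1363 with its block, 786 in DESeq2 with the block and 12 with the axis score, and 5 to 6 without 1 library. In mutants 7 became 80 in DESeq2, 329 with the block, 90 and 743 by the likelihood ratio test without and with it, 425 in DESeq2 with the block and 145 with the axis score, and 5 to 11 without 1 library (11 without either control female). Over both genotypes 7 became 12 by the likelihood ratio test with the block, and 5 to 8 without 1 library. The cause was not tested.

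Of the lists, 15 passed over both sexes, 4 in females, 20 in males, 22 in the interaction, 13 and 23 between the sexes in controls and in mutants, and 4 over both genotypes. With an estimated correlation 0 passed in each of the 7, and by fry 0 in each but 1 between the sexes in controls (adjusted p = 0.0211) and 1 over both genotypes (0.00270). The block gave 18, 7, 24, 25, 16, 22 and 5. It ended the calls of BMP targets in the interaction, cardiac muscle between the sexes in controls, and Notch and basal cell genes between the sexes in mutants, and brought in 3 lists in females (type 2 alveolar, interferon, hypoxia), 3 over both sexes (cell cycle, early response, TGF-β targets) and 4 in males (hypoxia, hedgehog, endothelial, interferon). It also brought in 4 in the interaction (hypoxia, lung transcription factors, TGF-β targets, inflammation), 4 between the sexes in controls (epithelial junction, endothelial, lung transcription factors, TGF-β targets), extracellular matrix in mutants and interferon over both genotypes. Apart from these and the values given beside the results, it changed no other list call. Without 1 library the counts were 10 to 22, 5 to 15, 18 to 22, 15 to 23, 8 to 16, 18 to 26 and 5 to 18.

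Over the named genes, 193 of 1103 values over both sexes, 53 of 228 in females, 199 of 1458 in males and 113 of 260 in the interaction passed where the value in the report did not. Conversely 144 in males, 9 of 133 in controls, 4 of 114 in mutants and 7 of 108 over both genotypes no longer passed, of which 137, 8, 4 and 7 left out a library.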

Other observations

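The relation of the cell cycle and type 1 alveolar scores and the axis score fits were tests chosen only after the result was seen, and Crym, Pkhd1, Mfsd2b and Golim4 were named after their values were seen. Over both sexes, Crym, a thyroid hormone binding protein, had a log2 change of 1.77 in mutants, Pkhd1, the fibrocystin gene of primary cilia, 1.48, Mfsd2b, a sphingolipid transporter, 1.11, and Golim4 0.59 ± 0.08 (SE, n = 4 against 4). None of the 4 passed the edgeR quasi-likelihood test (adjusted p = 0.158, 0.196, 0.158 and 0.158). In males Adamdec1 rose by 2.22 ± 0.18 (adjusted p = 0.00900), and Crispld2, a glucocorticoid-induced secreted protein, fell by 2.85 ± 0.40 (0.0282). Epha4 rose by 0.94 (0.020). These male calls were lost in the fits without mutant male 1 and without mutant male 2, where 0 of the 235 were called; 4 of the 235 were called without control male 1 and 86 without control male 2. The median absolute log2 change of the 235 was 1.38 and 1.24 without mutant males 1 and 2, against 1.30, and with the replicate block 235 were called in both fits.

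Further lists passed camera in the genotype comparisons, none with an estimated correlation. Granulocyte and mast cell genes were higher in mutants over both sexes (median 0.27, adjusted p = 0.00909, 0.684 with an estimated correlation) and in males (0.61, 0.0118, 0.562 with an estimated correlation), lost over both sexes without control male 2 (0.0912), mutant female 1 (0.0730) or mutant male 2 (0.0604) and in males without control male 2 (0.161). Neuroendocrine genes were lower over both sexes (-0.34, 0.0105, 0.684 with an estimated correlation) and in males (-0.42, 0.0437, 0.562 with an estimated correlation), lost without mutant female 1 (0.0601) or mutant male 2 (0.0731) and, in males, without control male 2 (0.0898) or mutant male 2 (0.169). Glucocorticoid response genes fell in mutant males (-0.49, 0.00187, 0.562 with an estimated correlation; 1 of 16 over all genes, 3 adjusted over the list alone, 10 over all genes with the replicate block) and passed in all 8 fits without 1 library. Fibroblast genes fell in mutant males (-0.08, 0.0310, 0.578 with an estimated correlation; 4 of 24 over all genes, 5 adjusted over the list alone), lost without control male 1 (0.218) or mutant male 2 (0.0740).

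A hypothesis is that libraries with more cycling cells hold less differentiated alveolar epithelium, whatever their group. Over the 8 libraries the cell cycle score and the type 1 alveolar score had Pearson's r = -0.798 (exact permutation p = 0.0190, adjusted 0.0380 over 4 relations tested) and Spearman's rho = -0.810 (exact permutation p = 0.0218, adjusted 0.0436). Without the 2 libraries farthest from the median cell cycle score, control male 1 and mutant female 1, r was -0.654 (n = 6). The type 2 alveolar score gave r = -0.901 (exact permutation p = 0.00126, adjusted 0.00506) and rho = -0.929 (0.00223, adjusted 0.00893), and r = -0.778 without these libraries. The club score (r = -0.550, exact permutation p = 0.161, rho = -0.667, p = 0.0831, r = -0.474 without them) and the ciliated score (r = -0.623, exact permutation p = 0.107, adjusted 0.142, rho = -0.667, r = -0.652 without them) did not pass. In all 4 groups replicate 1 had the lower cell cycle score and the higher type 1 and type 2 alveolar scores, so the replicate numbers enter the relation. With scores centred within replicate numbers and permuted only within them (576 permutations), r was -0.727 for type 1 (exact permutation p = 0.0938, adjusted 0.116) and -0.834 for type 2 (exact permutation p = 0.0122, adjusted 0.0486). The type 1 relation thus cannot be told apart from the difference between replicate numbers, with 4 libraries in each. A difference in maturity between embryos may lie behind r = -0.798, and the genotype and sex of the libraries also enter it.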
